A study of Mus musculus with 42 samples.

How the data were processed

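The values were RPKM from the authors' deposited tables, 1 table each for the TRAP, rTg4510 and miR-142 libraries, and levels are not compared across tables unless that is said. Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with HTSeq, and the versions were not given in the sources used here. Per the labels, the TRAP libraries were made by NuGEN amplification with RiboZero depletion and read as 50 bp pairs, and the cortex libraries by TruSeq Stranded with RiboZero Gold and read as 75 bp pairs. The lengths used for RPKM were recovered from the steps between the values of a gene. Of 18782 genes above 0 in any library, all 18782 gave whole numbers of reads within 0.005, 92.8% of the lengths were multiples of 3, and 80.6% lay within 5% of the coding length in GENCODE vM21, so the lengths are close to coding lengths. Depth is the number of reads recovered this way. No 2 libraries of the same group were duplicates, and pairs across groups were not checked.

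Gene tests used limma 3.58.1 in R 4.3.3 on log2 of RPKM plus 0.5, because RPKM are not counts, with the trend and robust options and an adjusted p (Benjamini-Hochberg) under 0.05. Genes needed at least 0.5 RPKM in at least 5 TRAP, 3 rTg4510 or 4 miR-142 libraries. Each TRAP region was set against the mean of the other 3. Errors after ± are standard errors for log2 fold changes and standard deviations for RPKM. Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, beside a run with the correlation estimated from the libraries and beside fry, where a list had at least 3 tested members. Counts over a list are given over all genes tested and adjusted over the list alone. The correlation of fold changes was tested by an exact permutation of the libraries within each table.

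The groups, the contrasts, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except that 2 alternatives were chosen after seeing the data: voom on the recovered reads, and leaving out spinal cord replicates 4 and 7. The coding length trend of each library was removed with a spline fit of its values on log2 length, and the test of the regional sets after this was chosen after seeing the data too. The rule named, in each comparison, the 8 genes with the highest and the 8 with the lowest fold change among those with an adjusted p under 0.05 and a mean of at least 2 RPKM in the higher group, leaving out predicted genes, and up to 4 members of each list with the smallest adjusted p, or 2 with the highest mean where none passed. The transgene and insertion genes, the neighbours of Mir142 and the Y-linked genes were named in any case, and where nothing was called, the 3 genes with the smallest p each way. The text gives a part of the genes so named, and some of them are not reported here.

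The steps were tested on simulated data with planted changes. At fold changes of 1.5, 2 and 4, the share called was 0%, 17.9% and 66.7% in the cortex TRAP comparison, 32.8%, 76.1% and 92.4% in the rTg4510 comparison and 76.1%, 88.1% and 98.5% between miR-142 null and wild type. Of the called genes 7.6%, 6.8% and 6.7% were unchanged ones. These changes were planted in genes outside the lists and above a minimum of reads. Each gene was drawn independently, without variation shared by the genes of a library, so these shares may not hold for the real calls. Gene positions came from RefSeq and 3' UTRs from GENCODE vM21, both on GRCm38. The remaining steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A weighted co-expression network was not analysed here, and neither was the microRNA itself.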

Results

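RNA was sequenced from 42 mouse libraries in 9 groups, and the values were reads per kilobase of gene model and per M reads (RPKM) for 20661 genes in 3 separate tables. The first table held 24 libraries of ribosome-bound RNA pulled down from mature oligodendrocytes, the myelin-forming cells of the central nervous system, by translating ribosome affinity purification (TRAP). Of these, 7 came from frontal cortex, 6 from subcortical white matter, 6 from cerebellum and 5 from spinal cord. The second table held 6 frontal cortex libraries of rTg4510 mice, which express mutant human tau in forebrain neurons and are a model of tauopathy, with 3 transgene-negative and 3 transgene-positive libraries whose titles carry the mark 8mo. The third held 12 prefrontal cortex libraries, 4 each from miR-142 null, heterozygous and wild-type mice. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Depth, recovered from the steps of the values, was 11.6 to 39.8 M reads in cortex TRAP libraries, 7.36 to 33.0 in white matter, 12.02 to 36.79 in cerebellum and 8.54 to 26.0 in spinal cord. It was 19.7 to 23.8 M reads in rTg4510-negative and 13.9 to 27.0 in positive libraries. In the third table it was 25.1 to 28.3 M in null, 25.4 to 31.8 in heterozygous and 22.8 to 26.5 in wild-type libraries. The series title names cortical oligodendrocyte genes, tauopathy and miR-142-3p, and the comparisons below follow those groups.

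The ribosome-bound RNA differed widely between the 4 regions. In limma's moderated F test, 6580 of 13982 genes tested (47.1%) differed at an adjusted p under 0.05. Myelin basic protein, Mbp, stood at 1930 ± 421 RPKM (SD, n = 7) in cortex, 7300 ± 2150 (n = 6) in white matter, 4230 ± 1450 (n = 6) in cerebellum and 16200 ± 3250 (n = 5) in spinal cord. Snap25, a synaptic protein of neurons, stood at 6020 ± 1940 RPKM in cortex, 4290 ± 1500 in white matter, 5040 ± 1340 in cerebellum and 4630 ± 855 in spinal cord, so neuronal transcripts were abundant in all 4 regions. Spinal cord replicates 4 and 7 stood apart from the rest of their group, with mean correlations of 0.797 and 0.796 to the other spinal cord libraries. They were also the shallowest of the group, at 8.54 and 9.79 M reads. Spinal cord replicates 3, 5 and 8 stood at 0.836 to 0.85, below the lowest value in the other regions (0.864, white matter replicate 7).

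**Figure D1:**
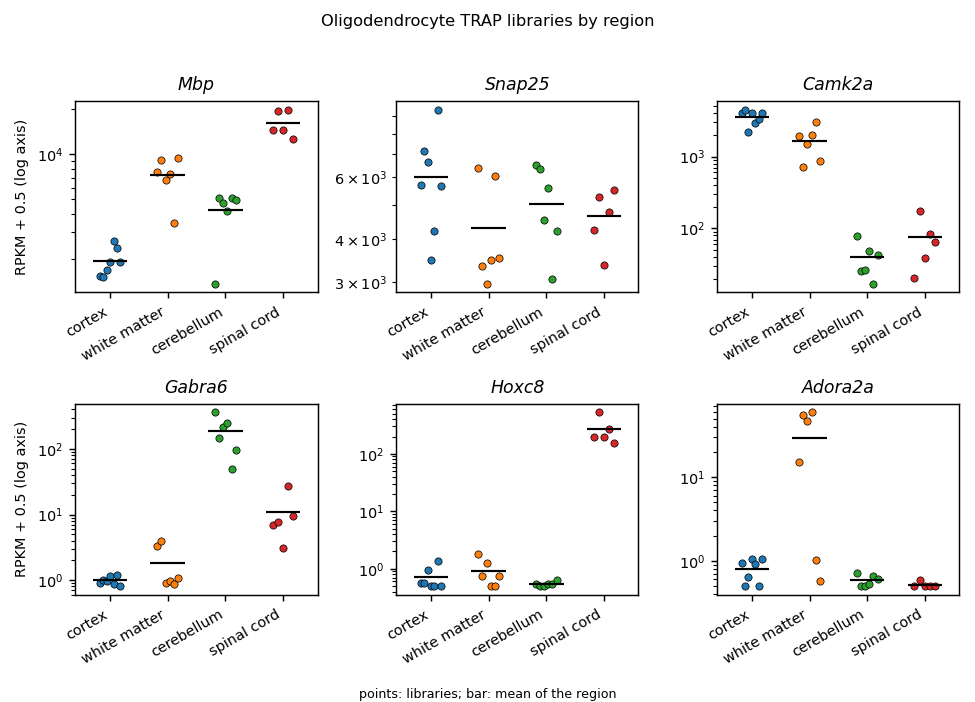
RPKM plus 0.5 on a log axis for Mbp, Snap25, Camk2a, Gabra6, Hoxc8 and Adora2a in the 24 TRAP libraries by region, with a point for each library and a bar at the mean of the region. Camk2a is high in cortex and white matter, Gabra6 in cerebellum, Hoxc8 in spinal cord, and Adora2a in 4 of the 6 white matter libraries.

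Frontal cortex was compared with the mean of the other 3 regions. The cortex TRAP libraries held less myelin RNA and more RNA of forebrain neuron genes, whichever cells that RNA came from. All 30 genes of the myelin list were lower (30 adjusted over the list alone), with a median log2 fold change of -1.87. Mbp changed by -1.99 ± 0.21 (SE, log2), the gap junction gene Gjb1 by -2.82 ± 0.37, and Olig2, a transcription factor of the oligodendrocyte lineage, by -2.02 ± 0.29. The list's camera call (adjusted p = 1.49e-20) was lost with an estimated correlation (adjusted p = 0.129). The serine protease gene Klk6, on the list of genes reported in disease-associated oligodendrocytes, stood at 1.89 ± 0.956 RPKM in cortex and 223 ± 76.3 in spinal cord (log2 fold change -4.40 ± 0.48). That list had 6 of 10 members lower (7 adjusted over the list alone), C4b and Serpina3n among them, with adjusted p = 0.129 with an estimated correlation. Of the forebrain excitatory neuron list, 14 of 15 genes were higher (15 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.00289). Camk2a, the calcium/calmodulin kinase of excitatory synapses, stood at 3570 ± 790 RPKM in cortex against 1670 ± 846 in white matter, 39.1 ± 22.2 in cerebellum and 75.4 ± 59.1 in spinal cord. The cortical transcription factor gene Tbr1 (log2 fold change 4.52 ± 0.25) and the potassium channel gene Kcnv1 (5.59 ± 0.24) also rose. Immediate early genes, which respond to neuronal activity, were higher in 10 of 12 (10 adjusted over the list alone), with Arc at 2.56 ± 0.20 and Npas4 at 2.81 ± 0.34 (adjusted p = 0.00289 with an estimated correlation). Synapse genes were higher in 17 of 21 (19 adjusted over the list alone, with 1 lower), among them Stx1a and Grin2b, with adjusted p = 0.0712 with an estimated correlation. Hox genes, which mark position along the body axis, were lower in 17 of 19 (17 adjusted over the list alone, adjusted p = 0.00289 with an estimated correlation). This call rests mainly on spinal cord. The mean log2 value of the Hox list was -0.89 in cortex, -0.81 in white matter, -0.36 in cerebellum and 3.72 in spinal cord. Cytosolic ribosomal protein genes were lower in 59 of 80 (62 adjusted over the list alone) and oxidative phosphorylation genes in 10 of 19 (10 adjusted over the list alone), with adjusted p = 0.227 and 0.336 with an estimated correlation. Of astrocyte genes, Slc1a2 was higher (1.25 ± 0.24) and Gfap lower (-1.55 ± 0.36), and of microglial genes Tmem119 was higher (1.86 ± 0.43). The Gfap call rests on spinal cord and white matter (350 ± 158 and 115 ± 94 RPKM). Gfap stood at 36.2 ± 34.3 RPKM in cortex and at 22.3 ± 11.7 in cerebellum. Over all genes tested, 2554 were higher and 2025 lower by limma at an adjusted p under 0.05, and 2378 and 2426 under quantile normalization. With the mean of the pan-neuronal list as a covariate C4b lost its call and the count was 2235, and with library weights 7273.

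Subcortical white matter shared the forebrain neuron genes and also carried striatal and ependymal transcripts. Of the striatal neuron list, 9 of 11 genes were higher (10 adjusted over the list alone, adjusted p = 0.0356 with an estimated correlation), including the dopamine receptor gene Drd1 (4.04 ± 0.61, log2) and the adenosine receptor gene Adora2a (4.11 ± 0.65). The mean log2 value of the striatal neuron list was 2.60 in white matter replicate 7 and 2.45 in replicate 8, against 5.66 to 7.32 in the other 4 white matter libraries. Ependymal genes, of the cells that line the ventricles, were higher in 4 of 6 (4 adjusted over the list alone, adjusted p = 0.049 with an estimated correlation), led by Ccdc153 (3.53 ± 0.44). The mean log2 value of that list ran from 0.01 in white matter replicate 7 to 4.04 in replicate 6. Forebrain excitatory neuron genes were higher in 10 of 15 (12 adjusted over the list alone), with Ddn at 5.10 ± 0.33, and immediate early genes in 4 of 12 (8 adjusted over the list alone), with adjusted p = 0.000421 and 0.0246 with an estimated correlation. Cerebellar neuron genes were lower in 11 of 14 (13 adjusted over the list alone) and Hox genes in 14 of 19 (17 adjusted over the list alone), with adjusted p = 0.00806 and 0.000105 with an estimated correlation. These calls rest on cerebellum and spinal cord, since the list means were no lower in white matter than in cortex (2.01 and 1.96 for cerebellar neuron genes, -0.81 and -0.89 for Hox genes). Hoxb8 and Hoxc8 lost their calls by voom. None of the 30 myelin genes passed the test, over all genes or over the list alone, and Mbp (0.51 ± 0.23, adjusted p = 0.21) passed under quantile normalization and under none of the other settings. S100b, a calcium-binding protein of glia, was lower than the mean of the other 3 regions (-1.94 ± 0.23), as were the neurofilament gene Nefh (-2.25 ± 0.29) and Klk6 (-2.50 ± 0.51). All of them were higher in spinal cord, which is part of that mean. Klk6 stood at 11.7 ± 16.9 RPKM in white matter against 1.89 ± 0.956 in cortex. Over all genes, 718 were higher and 240 lower by limma, and the split was 616 to 380 under quantile normalization.

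In cerebellum, genes of local neurons were higher, as were 3 of 6 choroid plexus genes, and forebrain genes were lower. All 14 cerebellar neuron genes rose (14 adjusted over the list alone, adjusted p = 0.00138 with an estimated correlation), among them the granule cell receptor subunit Gabra6 (184 ± 112 RPKM, n = 6, log2 fold change 6.05 ± 0.42), Cbln3 (6.03 ± 0.61) and the Purkinje cell gene Pcp2 (5.62 ± 0.66). Choroid plexus genes were higher in 3 of 6 (3 adjusted over the list alone), with the transthyretin gene Ttr at 5.14 ± 0.53 and Otx2 at 3.95 ± 0.40, and adjusted p = 0.0759 with an estimated correlation. Forebrain excitatory neuron genes were lower in 11 of 15 (12 adjusted over the list alone), immediate early genes in 8 of 12 (8 adjusted over the list alone, with 1 higher) and Hox genes in 7 of 19 (9 adjusted over the list alone). Their adjusted p values were 0.00138, 0.0137 and 0.021 with an estimated correlation. The Hox call rests on spinal cord, since cerebellum was no lower than cortex or white matter. The mean log2 value of the Hox list was -0.36 in cerebellum, -0.89 in cortex, -0.81 in white matter and 3.72 in spinal cord. Myelin genes were higher in 7 of 30 (10 adjusted over the list alone, with 1 lower), such as Anln (1.43 ± 0.31) and the transferrin gene Trf (1.53 ± 0.34), with adjusted p = 0.664 with an estimated correlation. Gpr17, a receptor of newly formed oligodendrocytes, was lower (-1.64 ± 0.36), on a list of which 4 of 10 genes were lower and 1 higher (the same counts adjusted over the list alone). Astrocyte genes moved both ways, with the glutamate transporter Slc1a3 higher (1.42 ± 0.32) and Slc1a2 lower (-2.57 ± 0.25). Over all genes, 850 were higher and 967 lower by limma, and 647 and 1132 under median-of-ratios scaling. With the pan-neuronal covariate Anln, Trf and Gpr17 lost their calls and the count was 891, and with library weights 4136.

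In spinal cord, Hox genes were higher, as were 5 of 8 genes of local neurons, and forebrain genes were lower. All 19 Hox genes rose (19 adjusted over the list alone, adjusted p = 1.4e-05 with an estimated correlation), led by Hoxc8 (269 ± 150 RPKM, n = 5, log2 fold change 8.52 ± 0.36) and Hoxd8 (8.10 ± 0.43). Genes of spinal cord and motor neurons were higher in 5 of 8 (5 adjusted over the list alone), including Prph (5.18 ± 0.54) and the vesicular acetylcholine transporter Slc18a3 (3.35 ± 0.51), with adjusted p = 0.123 with an estimated correlation. The myelin list had 16 of 30 genes higher (16 adjusted over the list alone), among them Mbp (2.10 ± 0.24) and Hapln2 (2.01 ± 0.41), with adjusted p = 0.474 with an estimated correlation. Genes reported in disease-associated oligodendrocytes were higher in 6 of 10 (7 adjusted over the list alone), with Klk6 at 4.38 ± 0.54, Serpina3n at 2.81 ± 0.52 and complement C4b at 2.15 ± 0.41, and adjusted p = 0.179 with an estimated correlation. Ribosomal protein genes were higher in 68 of 80 (68 adjusted over the list alone), with Rplp2 at 2.82 ± 0.25, and oxidative phosphorylation genes were higher in 10 of 19 and lower in 2 (the same counts adjusted over the list alone). Cholesterol synthesis genes were higher in 9 of 21 and lower in 2 (11 and 2 adjusted over the list alone), with Hmgcs1, of the first steps of the pathway, at 1.68 ± 0.25. The adjusted p values of these lists were 0.135, 0.282 and 0.394 with an estimated correlation. S100b (4.14 ± 0.25) and Gfap (350 ± 158 RPKM against 22.3 ± 11.7 in cerebellum), both on the astrocyte list, rose beside them, whichever cells that RNA came from. So did the neurofilament genes Nefm (2.26 ± 0.25), Nefh and Nefl. Forebrain excitatory neuron genes were lower in 13 of 15 (14 adjusted over the list alone) and immediate early genes in 10 of 12 (10 adjusted over the list alone), both with adjusted p = 0.0239 with an estimated correlation. Over all genes, 1765 were higher and 3592 lower by limma, with a median change of -0.33 that became -0.17 under median-of-ratios scaling (2354 higher, 2905 lower) and -0.04 under quantile normalization (2204 higher, 2459 lower). With library weights the count was 3537.

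Set directly against white matter, cortex carried less RNA of many myelin genes and of part of the striatal and ependymal lists. Myelin genes were lower in 21 of 30 (28 adjusted over the list alone), with Mbp at -1.88 ± 0.27 and the lineage factor Sox10 at -1.66 ± 0.34, and adjusted p = 0.179 with an estimated correlation. Striatal neuron genes were lower in 5 of 11 (8 adjusted over the list alone), such as Adora2a (-3.78 ± 0.77) and Drd2 (-3.58 ± 0.84), and ependymal genes in 4 of 6 (5 adjusted over the list alone), such as Ccdc153 (-3.77 ± 0.51). Their adjusted p values were 0.179 and 0.0658 with an estimated correlation. Adora2a stood at 0.518 and 0.0694 RPKM in white matter replicates 7 and 8, against 0.301 ± 0.248 in cortex. Higher in cortex were Cpne9 (3.87 ± 0.48), Tcap (3.63 ± 0.36), the interneuron peptide gene Vip (2.54 ± 0.48) and Nefm (1.35 ± 0.27). Over all genes, 295 were higher and 459 lower by limma. Adora2a, Drd2, Sox10, Vip and Nefm lost their calls with the pan-neuronal covariate, and Adora2a and Drd2 also by voom. The count was 54 with that covariate, 1158 under quantile normalization, 1378 with only these 2 groups in the fit and 2589 with library weights. It fell to 302 without white matter replicate 3, 474 without white matter replicate 8, and 478, 466 and 457 without cortex replicates 2, 5 and 8, and it was 1347 without spinal cord replicates 4 and 7.

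In the tau model, rTg4510-positive frontal cortex carried more RNA of microglia and of reactive glia than negative cortex. Of the disease-associated microglia list, 21 of 23 genes rose and 1 fell (21 and 1 adjusted over the list alone), and this was the list whose call held with an estimated correlation (adjusted p = 0.0415). Cst7, a cysteine protease inhibitor, went from 0.178 ± 0.229 to 16.7 ± 2.91 RPKM (SD, n = 3 in each group), and Clec7a, a pattern recognition receptor, from 0.46 ± 0.448 to 13.1 ± 2.38. The adaptor gene Tyrobp (log2 fold change 1.86 ± 0.10), the lysozyme gene Lyz2 (2.37 ± 0.15) and the lysosomal gene Cd68 rose as well. The member that fell, named after its value was seen, was the lipoprotein lipase gene Lpl (-1.29 ± 0.24), a call lost without negative replicate 1 or 3 or positive replicate 3. Complement and antigen presentation genes rose in 12 of 15 (15 adjusted over the list alone), with complement C4b going from 6.70 ± 0.917 to 56.0 ± 5.05 RPKM, C1qa at 1.92 ± 0.12 and H2-K1 at 1.69 ± 0.17, and adjusted p = 0.0627 with an estimated correlation. Homeostatic microglia genes rose in 11 of 17 (15 adjusted over the list alone), reactive astrocyte genes in 7 of 14 (9 adjusted over the list alone) and astrocyte genes in 5 of 14 (11 adjusted over the list alone). Their adjusted p values were 0.244, 0.189 and 0.186 with an estimated correlation. Gfap, the intermediate filament of reactive astrocytes, went from 126 ± 34.8 to 789 ± 74.6 RPKM, and the water channel gene Aqp4 rose by 0.96 ± 0.09. Of the disease-associated oligodendrocyte list 6 of 10 genes rose (8 adjusted over the list alone), and C4b, H2-K1, H2-D1 and B2m among them also stand on the complement and antigen presentation list (adjusted p = 0.0833 with an estimated correlation). Interferon response genes rose in 3 of 13 (13 adjusted over the list alone), with Ifitm3 at 1.55 ± 0.22 and adjusted p = 0.51 with an estimated correlation. The myelin list had 1 of 30 genes higher (1 adjusted over the list alone), the actin-binding gelsolin gene Gsn (0.63 ± 0.10), whose call was lost without negative replicate 1 or positive replicate 2 or 3.

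Neuronal genes moved both ways in rTg4510-positive cortex. Synapse genes fell in 8 of 21 (13 fell and 1 rose adjusted over the list alone), among them the presynaptic Rims1 (-0.53 ± 0.09) and the glutamate receptor subunit Grin2b (-0.57 ± 0.11), with adjusted p = 0.0627 with an estimated correlation. Forebrain excitatory neuron genes fell in 3 of 15 (7 fell and 1 rose adjusted over the list alone), namely Camk2a (-1.04 ± 0.17), Ddn (-1.18 ± 0.20) and Cux2 (-0.63 ± 0.12), with adjusted p = 0.246 with an estimated correlation. The calls of these 5 genes were each lost without negative replicate 1 or positive replicate 2 or 3, and those of Grin2b, Camk2a, Ddn and Cux2 also without negative replicate 3. GABAergic neuron genes rose in 2 of 9 (5 rose and 1 fell adjusted over the list alone), a list with a median of 0.73 that camera did not call (adjusted p = 0.143). Camera did not call the striatal neuron list (median 1.06, adjusted p = 0.406) or the spinal cord and motor neuron list (median 1.59, adjusted p = 0.0898) either. The mean log2 value of the striatal neuron list ran from 3.13 to 6.52 in negative libraries, with replicate 2 the highest. It ran from 4.86 to 5.83 in positive ones. The choroid plexus gene Ttr stood at 2120, 18.4 and 455 RPKM in the negative and at 8.81 to 22.6 in the positive libraries. The interneuron peptide genes Vip (0.66 ± 0.08) and Npy (1.05 ± 0.16) rose, with the call of Npy lost without positive replicate 2 or 3. The endogenous tau gene Mapt did not differ (387 ± 24.5 RPKM in negative and 380 ± 43.0 in positive libraries, adjusted p = 0.879), and the prion protein gene Prnp, whose untranslated sequences flank tau in the transgene, rose by 0.95 ± 0.11. Of 5 neighbouring genes on chromosome 12 that the transgene insertion of this line is known to affect, Wdr60 (-0.68 ± 0.15), Esyt2 (-1.02 ± 0.09), Ncapg2 (-0.94 ± 0.17) and Ptprn2 (-1.11 ± 0.10) fell, and Vipr2 rose (2.61 ± 0.57, adjusted p = 0.0426, 2.54 to 14.5 RPKM in the positive libraries), a call lost with a pseudocount of 1, under quantile normalization, by voom and without any single library but positive replicate 1. The calls of Wdr60 and Ncapg2 were lost without negative replicate 1 or 3 or positive replicate 2 or 3. They lie between positions 116077420 and 117278167 (GRCm38). Fgf14, at the other insertion site on chromosome 14, did not pass (-0.11 ± 0.29, adjusted p = 0.838). The 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at or below 0.118 RPKM in every positive library and at or above 9.77 in every negative library, so the sex of the animals and the genotype coincide in these 6 libraries. Over all genes, 806 were higher and 231 lower of 13972 tested by limma, and the split was 537 to 388 under median-of-ratios scaling and 433 to 325 under quantile normalization. The groups did not overlap for 31.6% of genes, against 10% by chance. The count was 5018 with library weights, and without single libraries it was 326 (negative replicate 1), 362 (negative replicate 3), 2406 (positive replicate 1), 282 (positive replicate 2) and 286 (positive replicate 3).

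**Figure D2:**
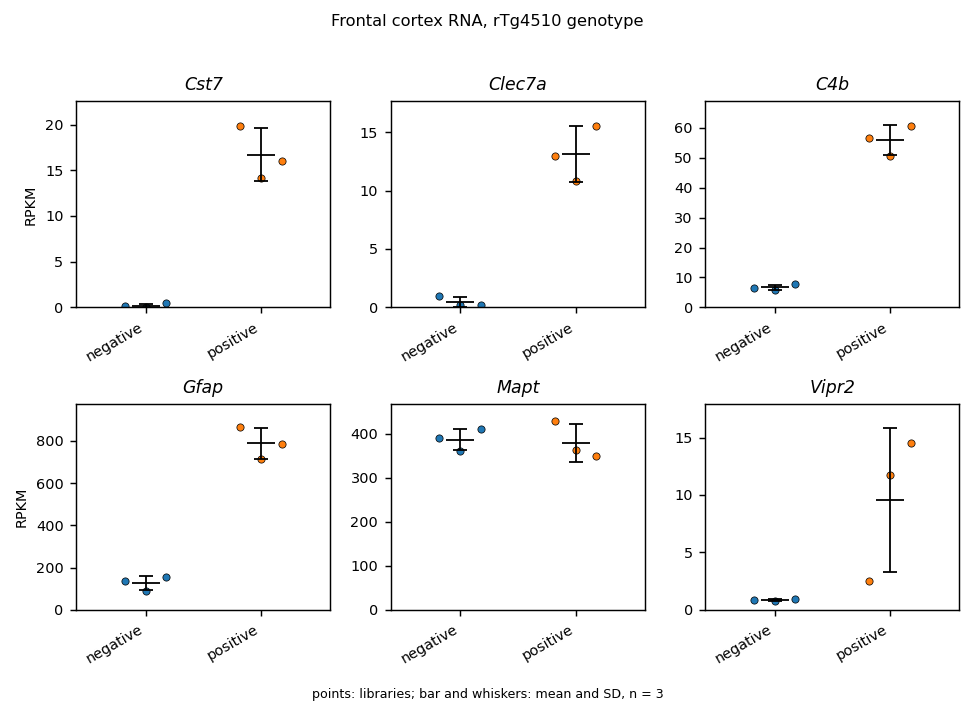
RPKM of Cst7, Clec7a, C4b, Gfap, Mapt and Vipr2 in the 3 rTg4510-negative and 3 positive frontal cortex libraries, with a point for each library and the mean with its SD. Cst7 and Clec7a are near 0 in negative libraries and above 10.8 in each positive library, and Mapt overlaps between the groups.

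**Figure D3:**
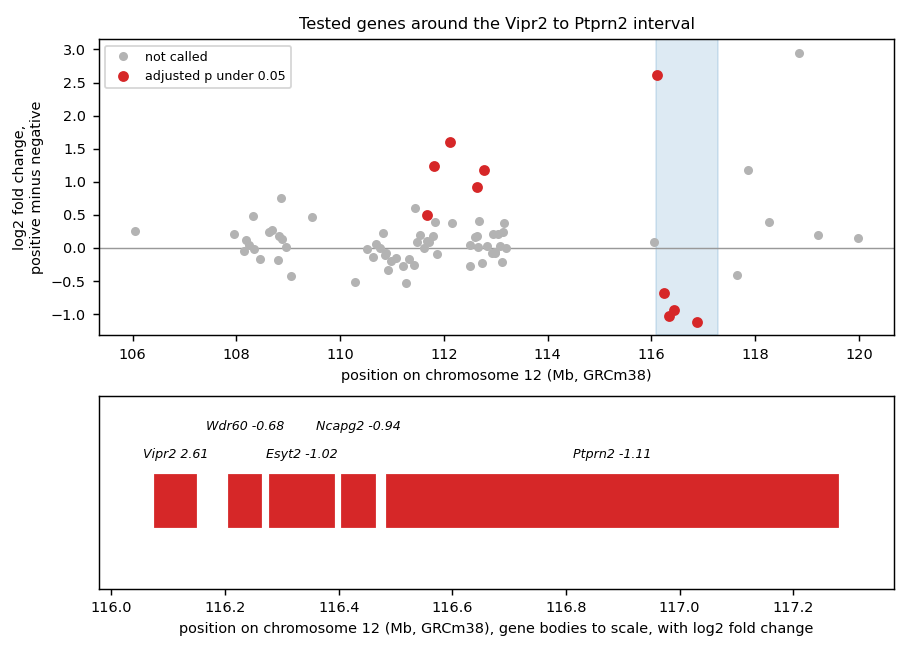
Log2 fold change of the tested genes on chromosome 12 around the Vipr2 to Ptprn2 interval against position in Mb (GRCm38), with called genes in red, and below it the 5 gene bodies to scale. Wdr60, Esyt2, Ncapg2 and Ptprn2 lie side by side and are lower in positive libraries, and 5 of 72 flanking genes are called.

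In the third table the targeted gene Mir142 was not analysed here, so the genotype labels had no direct check. Of its neighbours on chromosome 11, none passed in the null against the wild-type libraries, and Bzrap1 stood at -0.34 ± 0.10 (log2, adjusted p = 0.0788). The letter F or M in each title went with the 4 Y-linked genes in all 12 libraries. All 4 null titles carry the number 14 and no wild-type title does, so whatever that number stands for coincides with this comparison. Few genes were called between null and wild-type cortex, and the calls were fragile. Oprk1, the kappa opioid receptor gene, stood at 6.01 ± 1.52 RPKM in null, 5.42 ± 0.994 in heterozygous and 2.68 ± 0.722 in wild-type libraries (SD, n = 4 each). The upper-layer transcription factor gene Cux2 was lower (18.6 ± 2.59 in null against 29.1 ± 1.72 in wild type), and the deep-layer factor gene Fezf2 higher (0.45 ± 0.08). Endothelial genes were lower in 1 of 11 (8 adjusted over the list alone), the vascular growth factor receptor gene Flt1 (7.98 ± 1.72 in null against 13.5 ± 1.63 RPKM in wild type), with adjusted p = 0.562 with an estimated correlation. The pericyte and smooth muscle list, of another vascular cell type, had a median of -0.29 (camera adjusted p = 0.0413, and adjusted p = 0.788 with an estimated correlation), with Rgs5 at -0.46 ± 0.10 (adjusted p = 0.0514). Epas1, a hypoxia-responsive transcription factor gene, stood at 19.5 ± 0.809 in null against 27.4 ± 1.04 RPKM in wild type, and Eng, of the endothelial surface, fell by 0.70 ± 0.13. Of the synapse list, the scaffold genes Shank1 (-0.84 ± 0.16) and Dlg4 (-0.36 ± 0.07) were lower (2 of 21, and 6 adjusted over the list alone, adjusted p = 0.562 with an estimated correlation). Oxidative phosphorylation genes were higher in 0 of 19 over all genes by limma and in 17 adjusted over the list alone, with a median of 0.20 and adjusted p = 0.562 with an estimated correlation. With each library's trend on coding length removed, the median of this list was 0.14, and that of the ribosomal protein list went from 0.12 to 0.05. Uqcrb, a subunit of respiratory complex III that is not on that list, was higher (277 ± 19.2 against 211 ± 7.10 RPKM). None of the 30 myelin genes passed over all genes or over the list alone, and Mbp stood at 643 ± 128 in null against 520 ± 54.9 RPKM in wild type (adjusted p = 0.244). None of 14 reported miR-142-3p targets passed over all genes, and 1 was higher adjusted over the list alone, with a median of 0.04.

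Over all genes, 29 were higher and 36 lower of 13879 tested by limma, all at an adjusted p of 0.0493, and 3134 had an unadjusted p under 0.05. The count was 0 with a pseudocount of 1 RPKM or under median-of-ratios scaling, 2 without the filter, 6 without the trend and robust options, 41 with the title letter as a covariate, 177 among genes of a mean of at least 2 RPKM, 220 with only these 2 groups in the fit and 1297 with library weights, and under quantile normalization the split was 27 to 55. It was also 0 with the coding length trend removed, with 2949 genes at an unadjusted p under 0.05, and 1 with depth as a covariate. Leaving out any of the 12 libraries moved the count by more than 1.5 times, down to between 0 and 3 for 9 of them and up to 647, 697 and 651 without null replicate 2, heterozygote replicate 4 and wild-type replicate 1. Of the 16 called genes followed by the naming rule, 0 kept their call through all of these.

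Between heterozygous and wild-type libraries limma called 0 genes, with 1008 at an unadjusted p under 0.05, and 1 with library weights, 1 by voom on the recovered reads and 4 without heterozygote replicate 4. Epas1 had the smallest adjusted p (-0.46 ± 0.07, adjusted p = 0.144), and Fezf2 (0.47 ± 0.08, adjusted p = 0.313) and Oprk1 (0.91 ± 0.20, adjusted p = 0.674) did not pass. Between null and heterozygous libraries limma and voom called 0 genes, with 456 at an unadjusted p under 0.05. The interferon-induced gene Rsad2 (0.92 ± 0.18), the receptor gene Tgfbr1 (0.28 ± 0.07), whose 3' UTR holds 1 match to the miR-142-3p seed, and the lectin gene Cd209a (-0.83 ± 0.17) each had an adjusted p of 0.99. In these comparisons camera called 8 and 9 of 33 lists, and with an estimated correlation 0 in each.

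**Figure D4:**
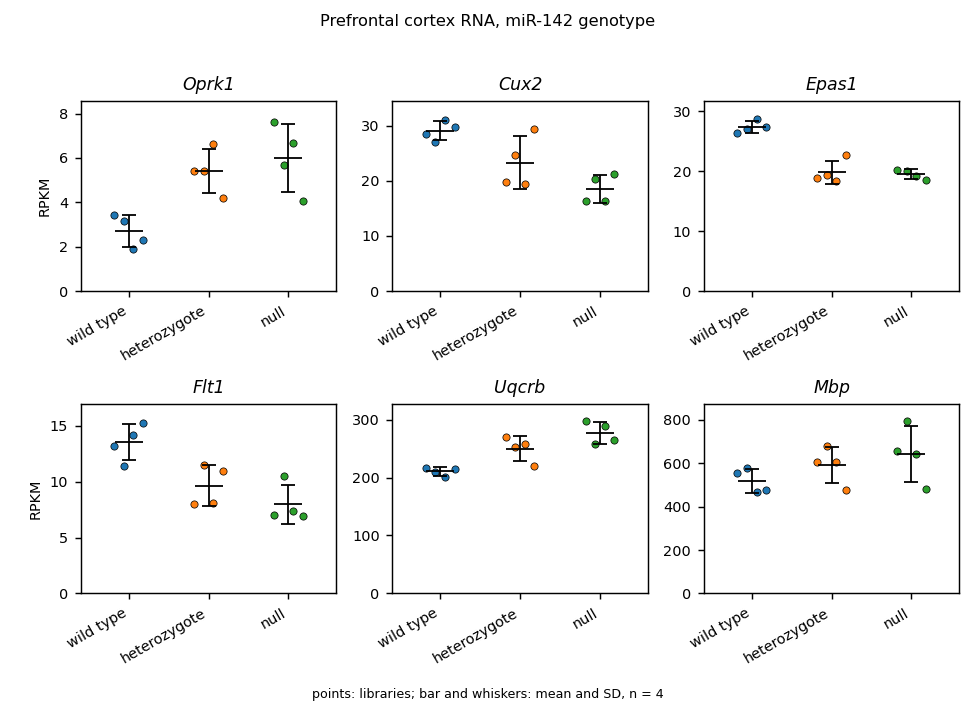
RPKM of Oprk1, Cux2, Epas1, Flt1, Uqcrb and Mbp in the 4 wild-type, 4 heterozygous and 4 null prefrontal cortex libraries, with a point for each library and the mean with its SD. Epas1 lies between 18.5 and 20.2 RPKM in null and between 26.3 and 28.8 in wild-type libraries, and Mbp overlaps between the genotypes.

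The genes that marked each region's TRAP libraries, whichever cells their RNA came from, were then followed in the bulk cortex comparisons. A gene was assigned to a region where it was higher there than in each of the other 3 regions by at least 1 on the log2 scale, which gave 166 genes for cortex, 39 for white matter, 163 for cerebellum and 513 for spinal cord. The sets hold genes of other cells, such as Arc and Vip for cortex, Adora2a and Ccdc153 for white matter and Gabra6 and Ttr for cerebellum. Lists of other cell types were counted together with the Hox, synapse, immediate early, complement and interferon lists. They hold 6 of the cortex, 7 of the white matter, 15 of the cerebellum and 30 of the spinal cord genes. Of these, 12 cerebellum genes are on the cerebellar neuron list and 17 spinal cord genes on the Hox list. These short lists do not name every neuronal gene. The myelin list holds 0 of the cortex genes. In rTg4510-positive cortex the cortex genes had a median change of -0.33, with 21 of 149 lower and 4 higher, and camera called them lower (adjusted p = 3.3e-17, and adjusted p = 0.0727 with an estimated correlation). The cerebellum genes (median 0.30, 12 of 131 higher) and the spinal cord genes (median 0.13, 40 of 485 higher and 2 lower) were called higher, with adjusted p = 0.629 and 0.314 with an estimated correlation. In miR-142 null cortex the cortex genes had a median of -0.12 and 2 of 157 were lower, and the spinal cord genes a median of 0.06 with 5 of 480 higher (camera adjusted p = 1.04e-06 and 0.000867). Both had adjusted p = 0.252 with an estimated correlation. The spinal cord set holds 38 ribosomal protein and 8 oxidative phosphorylation genes of the lists. With the coding length trend removed, its median in null cortex was 0.01 and its call was lost (adjusted p = 0.862), and the cortex set had a median of -0.08 (adjusted p = 0.000596). Of the 8 tests 5 were called, 3 where the sets needed a log2 difference of at least 2, 3 without rTg4510-negative replicate 1 or 2, and 0 with an estimated correlation.

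Across 13609 genes tested in both tables, the fold changes of rTg4510-positive against negative and of miR-142 null against wild-type cortex had a Spearman rho of 0.196 and a Pearson r of 0.26. Genes are not independent replicates, and in an exact permutation test over 1400 relabellings of the libraries the two-sided p was 0.24 for rho and 0.186 for r, with 0.00286 the smallest p that it can give.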

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

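The tests of Y-linked genes and of a lower neuronal share in the rTg4510 libraries, and those of the corrected lists with an estimated correlation and of the regional sets with the length correction, were chosen only after the results were seen. The values in this paragraph and the next come from libraries that lie far from the rest of their group, and 33 such values were found among 292 groups checked, where chance alone gives about 1 in 20 groups. List values are mean log2 RPKM, and the median of the other libraries follows in each case. Among TRAP libraries, cerebellum replicate 2 was low for Mbp (1360 RPKM against 4960), the disease-associated oligodendrocyte list (4.45 against 5.78), the ribosomal protein list (5.21 against 6.05) and the reported miR-142-3p targets (5.34 against 6.03). Cortex replicate 7 was low for homeostatic microglia (1.59 against 2.29) and synapse genes (6.57 against 7.12) and high for oxidative phosphorylation (7.33 against 6.39) and ribosomal protein genes (6.50 against 5.34). Cortex replicate 6 was high for the endothelial list (4.12 against 1.31) and Gfap (112 RPKM against 21.6). White matter replicate 2 was high for the cerebellar neuron list (3.48 against 1.82) and the ribosomal protein list (6.49 against 5.81), replicate 3 for Klk6 (45.8 RPKM against 6.44) and replicate 6 for Gfap (298 RPKM against 77.0). White matter replicate 7 was low for the Schwann cell list (1.72 against 3.43) and the heat shock list (3.68 against 4.96). Spinal cord replicate 7 was high for Gabra6 (26.6 RPKM against 6.82) and the Y-linked list (5.06 against 3.38) and low for the heat shock list (4.38 against 5.20). Spinal cord replicate 8 was high for the GABAergic neuron list (3.17 against 2.71), spinal cord replicate 4 for Adora2a (0.0952 RPKM against 0) and cerebellum replicate 8 for Hoxc8 (0.135 RPKM against 0.0374).

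In the miR-142 table, null replicate 2 was low for the astrocyte (6.79 against 6.99), reactive astrocyte (2.26 against 2.57) and homeostatic microglia lists (4.37 against 4.59) and high for the endothelial list (3.44 against 3.25) and Flt1 (10.5 RPKM against 7.02). Wild-type replicate 3 was low for the disease-associated microglia list (4.35 against 4.54) and the neighbours of Mir142 (4.38 against 4.48). Heterozygote replicate 2 was low for the disease-associated oligodendrocyte list (3.90 against 4.02), and heterozygote replicate 4 high for the complement and antigen presentation list (3.73 against 3.32). The Y-linked list was low in null replicate 1 (-1 against 4.67) and heterozygote replicate 4 (-0.92 against 4.57), whose titles carry the letter F.

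The first pattern is the RNA of neurons in the TRAP libraries. A difference in depth was argued against, since the forebrain excitatory list kept a median of 3.39 in cortex with depth as a covariate, against 3.38 without it. RNA of neurons carried along in the pulled-down material may be a source of it, and the test set the ratio of cortex TRAP to bulk wild-type cortex of the forebrain excitatory list against that of the pan-neuronal list. These ratios come from separately normalized tables, and they differed by -0.54, with an interval from -1.79 to 1.31 over resampled genes of the lists. By this test, this source and expression in the oligodendrocytes cannot be told apart. Between white matter libraries the mean log2 value of the striatal neuron list ran from 2.45 to 7.32. The ependymal list ran from 0.01 to 4.04 and the myelin list from 7.59 to 9.81. That wider spread argues against even expression in oligodendrocytes as the source of the striatal and ependymal RNA there. Relative to the bulk cortex, the median of the myelin list was higher by 2.32 (log2), and the medians of the neuronal lists stood at -0.11 (pan-neuronal), -0.42 (GABAergic), -0.66 (forebrain excitatory) and -0.71 (synapse). Those of the astrocyte, endothelial and homeostatic microglia lists stood at -1.20, -1.22 and -2.27.

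The second pattern is the set of genes called in rTg4510 cortex. The 4 Y-linked genes, at most 0.118 RPKM in positive and at least 9.77 in negative libraries, fit a difference of sex between the groups. For the other 992 calls compared, the F and M libraries of the miR-142 table argue only weakly against sex as the whole cause. The median change between them in the rTg4510 direction was 0.028 of the rTg4510 change, within the -0.136 to 0.107 of 96 relabellings. Those libraries came from other mice, and in the wild-type and heterozygous ones the letter coincides with the title number. An effect of sex that appears only with the tau transgene stays open. A lower share of neuronal RNA was argued against as the whole cause. The median of the disease-associated microglia list rose by 1.14 more than that of the myelin list. The interval of 0.76 to 1.74 resamples the genes of the lists and measures no spread between libraries. Per library, the mean log2 value of the microglia list ran from 3.83 to 3.91 in negative and from 5.38 to 5.54 in positive libraries. That of the myelin list ran from 5.93 to 6.44 in negative and from 6.23 to 6.37 in positive ones. A response of glia to the mutant human tau stays a candidate explanation. These libraries do not separate it from sex or from the gene changes at the chromosome 12 insertion.

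The third pattern is the higher ribosomal protein and oxidative phosphorylation lists. Between miR-142 null and wild type, the median of both lists fell from 0.128 to 0.06 when each library's trend on coding length was removed, so coding length bias may account for part of it. By camera at the preset correlation the lists still had adjusted p = 0.0373 and 1.78e-06 after this, but with an estimated correlation neither was called before it (ribosomal protein 0.788, oxidative phosphorylation 0.562) or after it (0.823 for each). Depth was argued against there as the source of the medians (0.127 with depth as a covariate), while limma's count of called genes went from 65 to 1 with that covariate and to 0 with the length correction (2949 at an unadjusted p under 0.05). In spinal cord the median stood at 1.034 after the length correction and 1.156 with depth as a covariate, against 1.225 without either, which argues against both as the whole cause, and a difference between the tissues stays open and untested, though these lists too were not called with an estimated correlation (0.128 and 0.231 after the length correction).

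Other splits of the same libraries were counted for each result. For the TRAP genes chance can be excluded over the 4 regions (6580 against at most 587 in the other splits, 1 of 100 splits as large), for cortex (4579 against 1012, 1 of 100), white matter (958 against 5, 1 of 100), spinal cord (5357 against 270, 1 of 100) and cortex against white matter (754 against 470, 1 of 100). For cerebellum chance is not taken as excluded (1817 against 2768, 2 of 100), since 1 other split called more genes than the real one. Between miR-142 null and wild type 1 of 35 splits gave as many genes (65 against 0), but all 65 stood at an adjusted p of 0.0493 and the count was 0 to 3 without any of 9 single libraries, so chance is not taken as excluded there. For heterozygous against wild type (0 against 32, 35 of 35) and null against heterozygous (0 against 7, 35 of 35) the real count is 0, so every split is as large and the count of splits says nothing about chance. The rTg4510 libraries have too few splits for a share under 0.05 (1037 genes against 1, 14 lists against 13 and 3 regional sets against 3, with 1, 1 and 4 of 10 splits as large). The other splits also called lists, with a median of 7 to 8 in the TRAP comparisons and 5.5 to 6 in the miR-142 ones. For the count of lists, chance is not taken as excluded in white matter (18 against 18, 2 of 100), where another split called as many. The count there was 13 without white matter replicate 5 or spinal cord replicate 8, and 6 with an estimated correlation. Chance cannot be excluded for the lists in cortex (15 against 16, 5 of 100), cerebellum (14 against 16, 6 of 100), spinal cord (13 against 17, 11 of 100) or cortex against white matter (12 against 14, 15 of 100). Nor can it be excluded for the lists of null against wild type (9 against 13, 6 of 35), heterozygous against wild type (8 against 10, 11 of 35) and null against heterozygous (9 against 15, 5 of 35), or for the regional sets in null against wild type (2 against 3, 13 of 35).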

How the results depend on the processing

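The alternatives with voom on the recovered reads and without spinal cord replicates 4 and 7 were chosen only after the data were seen. Over 267 named gene results, 2872 of 3020 comparisons with another setting kept the side of the threshold, 136 lost the call and 12 gained it. Of 4842 with 1 library left out, 4580 kept it. Direction was compared only where a result was called in either setting, and a result called in neither counted as kept. Over 297 list results the numbers were 1682 of 1815, and 5197 of 5346 with 1 library left out. No result reversed. With an estimated correlation the called lists went from 15 to 3 in cortex, 18 to 6 in white matter, 14 to 4 in cerebellum, 13 to 3 in spinal cord, 12 to 0 in cortex against white matter, 14 to 1 in rTg4510, and 9, 8 and 9 to 0 in null against wild type, heterozygous against wild type and null against heterozygous, because camera then allows for the correlation within each list. With library weights the counts of genes were 7273 in cortex, 4136 in cerebellum, 3537 in spinal cord, 2589 in cortex against white matter, 5018 in rTg4510, 1297 in null against wild type and 1 in heterozygous against wild type. With the pan-neuronal covariate they were 2235, 891 and 54 in cortex, cerebellum and cortex against white matter. Cortex against white matter gave 1158 under quantile normalization, 1378 with only the groups compared and 1347 without spinal cord replicates 4 and 7. Null against wild type gave 0 with a pseudocount of 1, 0 under median-of-ratios scaling, 2 without the filter, 177 with a mean of at least 2 RPKM, 6 without trend or robust options, 41 with the title letter as covariate and 220 with only the groups compared, and heterozygous against wild type gave 1 by voom. Of the regional sets 3 were called with a log2 fold change of at least 2, 3 with sets from the replicate block fit and 0 with an estimated correlation, against 5. Apart from the estimated correlation the cause was not tested.

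The ranges with 1 library left out were 6014 to 6836 genes over the 4 regions, 3855 to 4945 in cortex, 667 to 1106 in white matter, 1347 to 2005 in cerebellum, 4871 to 5452 in spinal cord and 302 to 1032 in cortex against white matter. They were 282 to 2406 in rTg4510, 0 to 697 in null against wild type, 0 to 4 in heterozygous against wild type and 0 to 0 in null against heterozygous (limma, 456 genes at an unadjusted p under 0.05, voom 0). The regional sets ranged from 3 to 6 and the Spearman rho from 0.123 to 0.272. The replicate block, by title number, gave 4626 genes in TRAP cortex against the mean of the other 3 regions. The numbers were not taken as pairs, although the titles reuse them across regions, since the labels give no shared animal. The rule set beforehand also needed a correlation above 0.1 in every same-number pair, and 13 of 31 reached it. Among pairs of different numbers 24 of 184 did, so same-number pairs reached it more often. The median correlations were 0.06 for same and -0.0215 for different numbers. With 7 of 24 libraries going best with their own number, shared animals for some numbers stay open. With 7.36 to 39.8 M reads in the TRAP libraries, depth may limit the genes of low RPKM there, which was not tested.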

Other observations

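In this part the count of lower calls among neighbouring genes was chosen only after the result was seen. A first hypothesis was that loss of miR-142-3p raises transcripts whose 3' UTR matches its seed. Of 13879 genes tested between null and wild type, 13372 (96.3%) had an annotated 3' UTR, and 966 of these held the 7-base match ACACTAC. Within bins of 3' UTR length, genes with a match were higher by 0.0055 (log2) than genes without (permutation p = 0.216 over 100000 draws), and 52 of 139 other 7-base sequences gave a difference as high. Relabelling the libraries gave a difference as high in 1 of 70 cases (exact one-sided p = 0.0143), and the 435 genes with the 8-base match ACACTACA differed by 0.0124. A shift of 0.05 planted in the same genes was recovered as 0.0488, so a shift of that size would have been seen, and these data argue against one. Smaller shifts, and shifts in rare cells of the cortex, stay open.

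A second hypothesis was that the lower genes on chromosome 12 in rTg4510 cortex belong to a wider segment that differs between the genotypes. Of 72 tested genes within 10 Mb of Vipr2, Wdr60, Esyt2, Ncapg2 and Ptprn2, 5 were called (6.9%), against 7.4% of all genes. This argues against a segment that fills the whole window. All 5, named after their values were seen, were higher and lay close together (Ckb, Xrcc3, Aspg, Adssl1 and Pld4, positions 111669355 to 112768986). No tested gene with a known position lay between 113189523 and 116047714, so the share says little about a shorter segment. Wdr60, Esyt2, Ncapg2 and Ptprn2 gave 4 lower calls in 10 neighbouring genes, and 69 of 1000 permuted gene orders gave as many somewhere in the genome.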
